A study of Homo sapiens with 4 samples.

How the data were processed

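ATF3 binding was profiled by CUT&Tag in SW480 cells, an established line from a colorectal adenocarcinoma. In CUT&Tag an antibody brings a transposase to chromatin, which cuts and tags the DNA around the bound protein. Cells were kept for 24 h in full medium or in medium restricted in cystine, the oxidised form in which cells import cysteine, and each medium had 2 libraries. About the origin of the 2 libraries of a medium the labels say only that they are separate samples, so the p-value for peak numbers measures only the spread between these samples, which may be technical. The other p-values are over regions or chromosomes and do not measure the spread between samples. No library made without the ATF3 antibody was used here.

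The deposited data are 4 peak lists, with peaks listed separately for each library, in the narrowPeak layout of MACS2. Per the submitters' processing notes, bcl2fastq 2.17, fastp 0.19.7, BWA 0.7.17 and MACS2 2.2.7.1 were used and the genome build was hg19. The options of the peak caller are not given in the sources used here. In the deposited lists each peak has a position, a fold enrichment (a ratio of the summit pileup to the expected local pileup), a −log10 p, a −log10 q and a whole-number score that is 10 times the −log10 q. Every listed −log10 q was at least 1.30, the value of a q of 0.05. These scores and folds are the authors' own and belong to a single list. As such they were used to describe, rank and filter peaks within a list. Pileups worked out from the folds and −log10 p, as described below, were also compared between libraries.

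The files give no read counts, and what they do hold allowed the depth to be worked out. MACS2 computes the fold as (pileup + 1)/(background + 1) and the p-value from the Poisson chance of a larger pileup, so a fold and a p-value together fix both the pileup and the background. A whole-number pileup matched the deposited −log10 p within 0.1% for 100% of peaks in each library. The local background of 100% of peaks was either one fixed value or a whole multiple of 0.015, within 0.1 of a step, which is what 150 bp tags counted over 10 kb give. The fixed value, the lowest background in a list, is the expected pileup over the whole genome and is proportional to the number of tags kept. With the peak caller's usual human genome size of 2.7 Gb, which is an assumption here, it corresponds to 23.4 and 19.5 M tags for cystine-restricted replicates 1 and 2, and to 19.9 and 23.7 M tags for full-medium replicates 1 and 2. On simulated pileups drawn from these lists and written with the same number of digits, 100% of 19974 were recovered exactly.

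Peaks on chromosomes 1 to 22 and X were compared. Peaks on chromosome Y and on unplaced or alternate contigs were counted apart. The 4 lists were joined into regions by merging peaks that shared at least 1 bp, and bedtools 2.31.1 gave the same number of regions as the merging used here. A region was called gained if it had a peak in both cystine-restricted libraries and in neither full-medium library, and lost in the reverse case. Gained and lost regions were also planted in simulated lists at the positions of these peaks. The number called gained was 99.7% of the 11229 planted, and the number called lost 99.6% of the 2237 planted. The planted peaks were only shifted slightly and none was dropped at a threshold. This checks the merging and counting, and not the loss of peaks near the caller's threshold. Regions found in both libraries of a medium were ranked by the lower of their 2 rank percentiles of −log10 p and parted into 10 strength deciles. Shares carry 95% Wilson intervals, which cover counting error over regions only. Peak numbers were compared by a two-sided exact permutation test. Chromosomes were compared by two-sided Fisher's exact tests on regions with Benjamini-Hochberg adjustment, and regions are not independent replicates. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

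The tests, the alternatives and the rule for named regions were fixed before the data were examined. The alternatives were a −log10 q of at least 5, the same number of top peaks from each library, a reciprocal overlap of at least 50%, leaving out each library in turn, the replicate number as a block, and leaving out the 1% of regions with the highest fold enrichment. The rule named CBS, ATF3 and SLC7A11, members of the gene lists and the strongest genes, and, where no annotation of the build of the peaks is used, regions by position in their place. These were the 10 strongest gained, the 5 strongest lost and the 5 strongest regions present in all 4 libraries, by the lowest rank percentile among the libraries that have the peak. The recovery of pileups, the chromosome comparison with its alternatives, a −log10 p of at least 5 and a pileup of at least 10 times the background were added after the data were seen. The planned comparisons of distance to transcription start sites, of 14 gene lists, of sequence motifs and of the CBS locus needed an hg19 annotation or sequence and were not analysed here. The gene table used here is of GRCh38, and only its gene symbols, the class (protein-coding or other) and the chromosome of each gene were taken from it. Values per Mb take the end of the last listed peak on a chromosome as its length.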

Results

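ATF3 is a stress-induced transcription factor of the bZIP family. Its binding was mapped by CUT&Tag in SW480 colorectal cancer cells after 24 h in full medium or in cystine-restricted medium, with 2 libraries per medium. The comparison asks where ATF3 signal differs when cystine, and with it the supply of cysteine for glutathione, is limited. The genome background pileup, which is proportional to the number of tags kept, was 1.30 and 1.08 tags in cystine-restricted replicates 1 and 2 and 1.11 and 1.32 tags in full-medium replicates 1 and 2. The media had nearly the same mean, 1.19 ± 0.15 and 1.21 ± 0.15 tags (SD, n = 2 each).

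More ATF3 peaks were listed under cystine restriction. On chromosomes 1 to 22 and X the cystine-restricted libraries had 33838 and 29607 peaks and the full-medium libraries 17447 and 19132 peaks, which gives means of 31722.5 ± 2992 and 18289.5 ± 1191 (SD, n = 2 each) and a ratio of 1.73. Each cystine-restricted library had more peaks than each full-medium library, with ratios from 1.55 to 1.94. The peaks covered 15.3 ± 2.0 Mb under cystine restriction and 8.11 ± 0.52 Mb in full medium (SD, n = 2 each), with median widths of 415 and 392 bp against 377 and 376 bp. The median fold enrichment, which describes each list by itself, was 5.24 and 5.28 in cystine-restricted replicates 1 and 2 and 5.30 and 5.05 in full-medium replicates 1 and 2. The difference in number was larger than the spread between libraries of a medium, but 2 libraries against 2 allow only 6 assignments, and the two-sided exact permutation p was 0.33, the smallest this design can give.

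**Figure D1:**
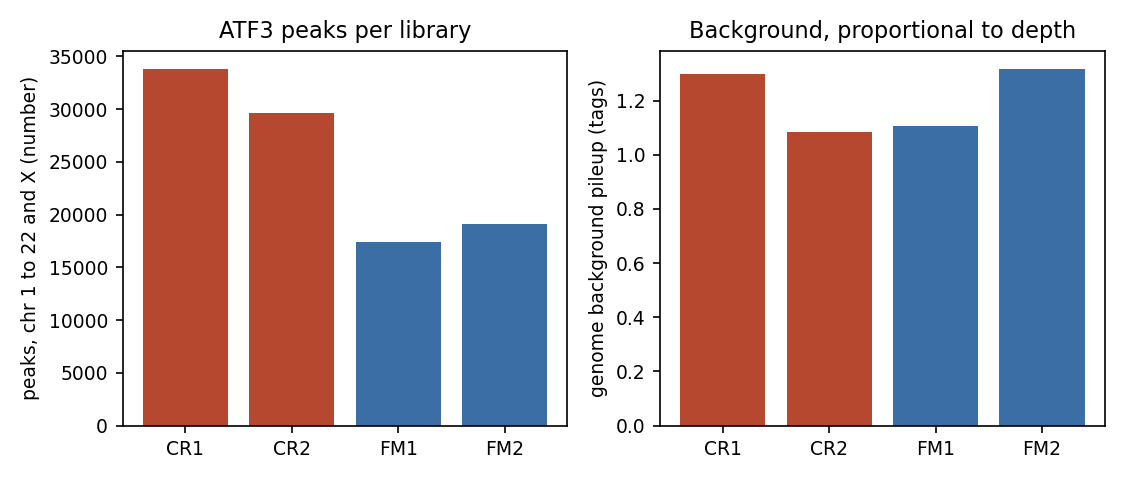
The left panel plots the number of peaks per library on chromosomes 1 to 22 and X, and the right panel the genome background pileup in tags, for cystine-restricted (CR1, CR2) and full-medium (FM1, FM2) libraries, 1 bar per library. The cystine-restricted bars, 33838 and 29607, are above the full-medium bars, 17447 and 19132, while the background pileups, 1.08 to 1.32 tags, do not separate the media.

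The full-medium peaks were for the most part contained in the cystine-restricted lists. Of the 17447 peaks of full-medium replicate 1, 84.4% overlapped a peak of cystine-restricted replicate 1 and 79.97% one of cystine-restricted replicate 2, but only 67.7% overlapped a peak of the other full-medium library. Of the 19132 peaks of full-medium replicate 2, the shares were 81.2%, 76.3% and 61.2%. In the other direction, 41.2% and 43.9% of the peaks of cystine-restricted replicate 1 were found in full-medium replicates 1 and 2 and 63.9% in the other cystine-restricted library. For cystine-restricted replicate 2 these shares were 45.2%, 47.7% and 74.0%. Measured in covered bases, the Jaccard index was 49.8% between the cystine-restricted libraries, 45.4% between the full-medium libraries, and 35.9% to 40.1% for the 4 pairs across media. No test of these indices was run, since the 3 ways to part the libraries allow no p under 0.33. With the same number of top peaks taken from each library, the excess of the share found in cystine-restricted libraries over that found in the other full-medium library shrank from 16.0 to 3.92 percentage points, and with a reciprocal overlap of 50% to 6.53 percentage points.

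The 4 lists merged into 44826 regions. Of these, 10331 had a peak in all 4 libraries, 5685 were gained (in both cystine-restricted and neither full-medium library) and 173 were lost (the reverse). Gained regions made up 27.6% of the 20633 regions reproducible under cystine restriction, and lost regions 1.56% of the 11121 reproducible in full medium. Parting the libraries across the media gave far fewer regions of the same kind: 781 in replicate 1 of each medium alone, 460 in replicate 2 of each medium alone, and 1002 and 381 when the numbers were crossed. Gained regions were narrower than those in all 4 libraries, with median widths of 475 and 888 bp. These are widths of merged regions, which can only widen as peaks of more libraries are joined, so the contrast is at least partly built in. Regions of the pairs mixed across the media, which also join peaks of 2 libraries, had median widths of 379.5 to 417 bp. Peak widths within single libraries were not compared between these classes. Gained regions also had a lower median fold enrichment. It was 5.19 against 7.42 within the list of cystine-restricted replicate 1, and 5.00 against 7.09 within that of replicate 2. Lost regions had a median width of 401 bp. With the same number of top peaks from each library, 1840 regions were gained and 752 lost, and with a reciprocal overlap of 50%, 5271 were gained and 859 lost. At a −log10 q of at least 5, 4342 were gained and 85 lost. A pileup of at least 10 times the background, a cutoff added after the data were seen, gave 5264 gained and 87 lost. Leaving out a library loosens the definition: 12857 regions were gained and 628 lost without cystine-restricted replicate 1, 15954 and 369 without replicate 2, 7691 and 2838 without full-medium replicate 1, and 8346 and 2035 without full-medium replicate 2.

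**Figure D2:**
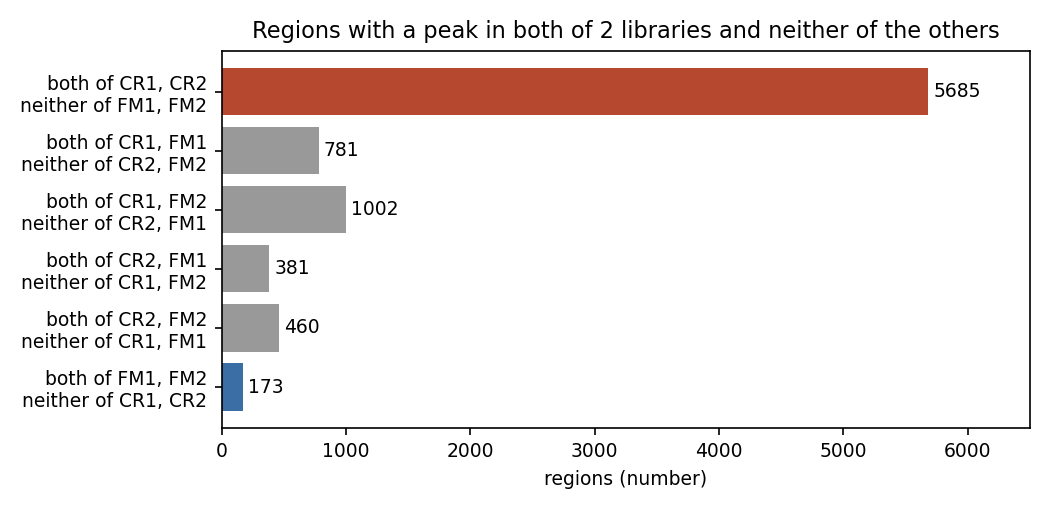
The bars give the number of merged regions with a peak in both of 2 libraries and in neither of the others, for the 6 ways to choose the libraries (CR, cystine-restricted; FM, full medium). The cystine-restricted pair has 5685 such regions, the full-medium pair 173, and the mixed pairs between 381 and 1002.

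The regions that were absent from full medium were mostly weak ones. Among the weakest decile of reproducible cystine-restricted regions, 64.2% (95% Wilson interval 62.1 to 66.3) had no full-medium peak, and the share fell in each decile to 30.0% (28.1 to 32.0) in the fifth, 7.22% (6.18 to 8.42) in the eighth and 0.339% (0.164 to 0.698), or 7 of 2064 regions, in the strongest. For reproducible full-medium regions the share with no cystine-restricted peak was 7.46% (6.06 to 9.16) in the weakest decile, 0.809% (0.426 to 1.53) in the fifth, and 0 of 1113 in the strongest, with an upper Wilson limit of 0.344%. The deciles rank the regions of each medium among themselves, so a decile is not the same strength in both media. In the weakest decile, the share gained was 37.2% and the share lost 27.3% with the same number of top peaks from each library, and with a reciprocal overlap of 50% they were 68.2% and 26.2%. In the strongest decile, the shares gained and lost were 0.307% and 0% with the same number of top peaks. With a reciprocal overlap of 50% they were 2.89% and 0.346%. A peak that is not listed is one that did not meet the caller's criteria in that library, so absence is not a measurement of no binding.

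**Figure D3:**
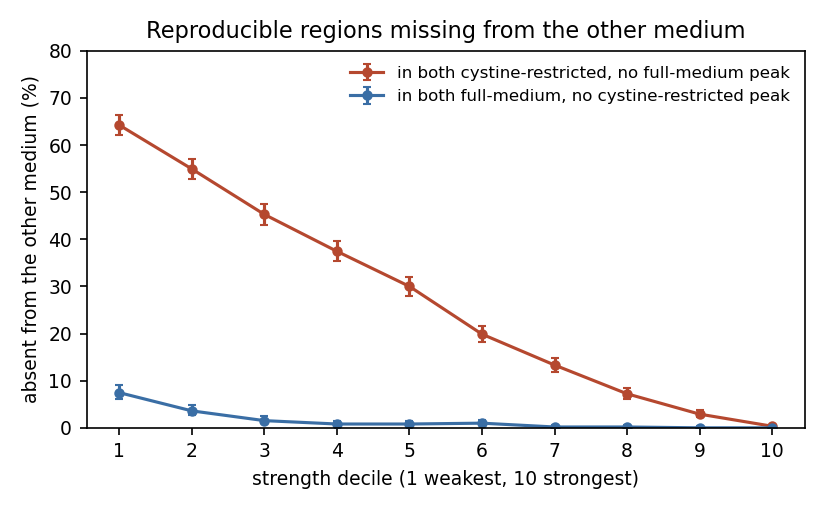
The share (%) of reproducible regions with no peak in either library of the other medium is plotted against strength decile, for regions found in both cystine-restricted and in both full-medium libraries, with 95% Wilson intervals as error bars. The cystine-restricted curve falls from 64.2% to 0.339%, and the full-medium curve from 7.46% to 0.

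The strongest gained region lay on chromosome 21 from 40823836 to 40825120 (hg19), 1285 bp wide, with a fold enrichment of 12.06 and 12.05 and a −log10 q of 56.3 and 45.4 in cystine-restricted replicates 1 and 2. A second region on chromosome 21, from 41214410 to 41215374, ranked next after 3 others, with a fold of 11.7 and 11.3. These 3 were on chromosome 10 from 73025781 to 73026796, with a fold of 11.5 and 11.2, on chromosome 17 from 10350374 to 10351176, with a fold of 14.97 and 13.94, and on chromosome 1 from 183577276 to 183577966, with a fold of 11.5 and 12.2. The next were on chromosome 12 from 121581749 to 121582730, chromosome 6 from 41254131 to 41254997, chromosome 7 from 106065385 to 106066169, chromosome 8 from 28982660 to 28983449 and chromosome 2 from 6118349 to 6119363, with folds between 8.80 and 12.7. The summit pileups of the first region were 78 and 62 tags, against genome backgrounds of 1.30 and 1.08, and no full-medium peak overlapped any of these 10 regions. The folds and −log10 q are the authors' per-peak values, the positions and widths are those of merged regions, the pileups and backgrounds were recovered from the lists, and the genes at these positions were not analysed here.

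The strongest lost region was a 179 bp region on chromosome 2 from 62633576 to 62633754, with a fold enrichment of 8.40 and 13.4 in full-medium replicates 1 and 2. It was followed by chromosome 20 from 48809360 to 48809790, with a fold of 4.08 and 3.27 at summit pileups of 74 and 65 tags, and chromosome 19 from 3929810 to 3930281, with a fold of 7.42 and 6.61. The folds on chromosome 20 were low for such pileups because the local background was high. A higher local background can also keep a region off a list, and whether this happened under cystine restriction was not analysed here. The remaining ones were on chromosome 5 from 159301498 to 159301648 and on chromosome 7 from 103063899 to 103064530, with folds between 5.65 and 7.33. The regions that ranked highest in all 4 libraries were on chromosome 18 from 107508 to 108675 and from 108854 to 111167, on chromosome 1 from 121484286 to 121485509, on chromosome 7 from 61968641 to 61969741 and on chromosome 4 from 49151278 to 49151923. The first of these had a −log10 q between 1024 and 1744 at a fold of only 5.04 to 5.24, since its local background was high as well, and the chromosome 4 region had folds of 27.0 to 28.2. Peaks were not filtered for repeated sequence, and whether these high pileups come from it was not analysed here.

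CBS encodes cystathionine beta-synthase, which takes homocysteine into the transsulfuration route to cysteine, and is named with ATF3 in the title of the series. It lies on chromosome 21, where 91 regions were gained, 3 lost and 173 present in all 4 libraries. ATF3 itself lies on chromosome 1, with 522 gained, 4 lost and 853 common regions, and SLC7A11, the cystine transporter gene, on chromosome 4, with 204 gained, 3 lost and 264 common regions. Whether any of these regions belongs to CBS, ATF3 or SLC7A11 was not analysed here.

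Gained regions were found on each of the 23 chromosomes and outnumbered lost ones on each, but their share differed between chromosomes. The share was lowest on chromosome 19, where 205 of 1117 reproducible cystine-restricted regions, or 18.4% (95% Wilson interval 16.2 to 20.7), were gained. It was highest on chromosome 15, with 205 of 568, or 36.1% (32.2 to 40.1), followed by chromosome 4 with 34.5% (30.7 to 38.4) and chromosome 6 with 32.6% (29.4 to 36.0). Chromosomes 17, with 296 of 1287 (20.8% to 25.4%), and 11, with 23.9% (21.6 to 26.4), were below the pooled share of 27.6%. These 6 chromosomes passed Fisher's exact test against the rest, with Benjamini-Hochberg adjusted p of 5.3e-12 for chromosome 19, 8.2e-05 for chromosome 15, 0.0011 for chromosomes 4 and 17, 0.0063 for chromosome 6 and 0.011 for chromosome 11, and the other 17 did not. The share on chromosome 21, 27.3% (22.8 to 32.4), was not distinguishable from the rest, with an adjusted p of 0.97 in the same Fisher's exact tests. Without cystine-restricted replicate 1 or 2, the gained share was 34.5% or 39.5% on chromosome 19, 50.5% or 54.4% on chromosome 15 and 44.4% or 48.0% overall. Without full-medium replicate 1 or 2 it was 28.4% or 30.2%, 45.6% or 50.4%, and 37.2% or 40.4%, and with the same number of top peaks from each library 8.89%, 20.8% and 14.1%. The tests are over regions and not over libraries, and the comparison was chosen after the data were seen.

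**Figure D4:**
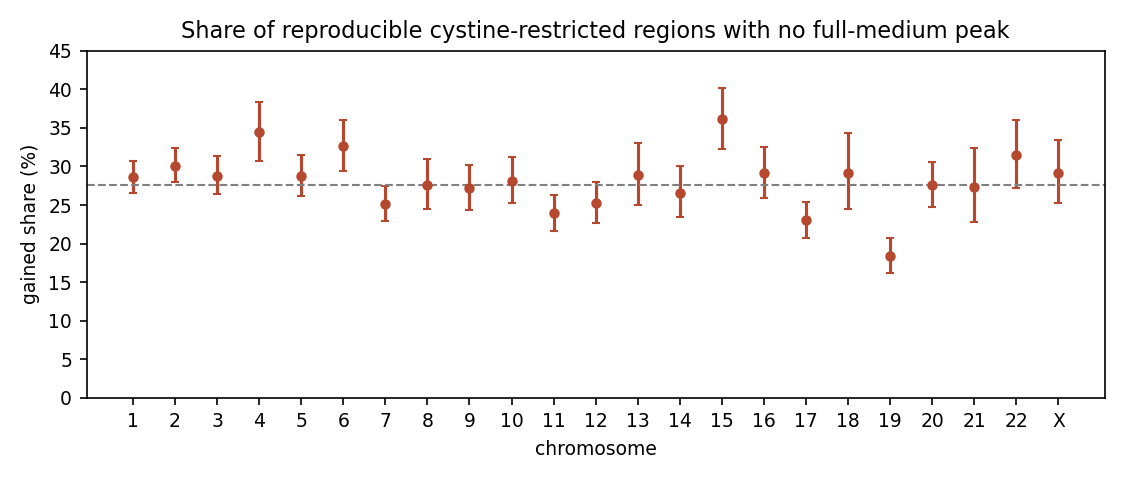
The gained share (%) of reproducible cystine-restricted regions is plotted for each of the 23 chromosomes with 95% Wilson intervals, and the dashed line marks the pooled share of 27.6%. Chromosome 19 lies lowest at 18.4% and chromosome 15 highest at 36.1%.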

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

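The peak numbers below had been seen when the test of their height was chosen, and its result had not. Peaks outside chromosomes 1 to 22 and X were flagged because the comparisons above do not use them. Chromosome Y and the unplaced or alternate contigs, which hold much repeated sequence, had 302 and 296 peaks in cystine-restricted replicates 1 and 2 and 250 and 263 in full-medium replicates 1 and 2. Their number differed between the media by a ratio of 1.17, against 1.73 on the other chromosomes, and of their 395 merged regions 178 were in all 4 libraries, 23 were gained and 5 lost. Reads of multi-copy sequence that has nothing to do with the medium were predicted to keep their height. At the 178 regions the median log2 change of the summit pileup over the genome background was 0.58 (interquartile range 0.20 to 0.79). This was close to the 0.53 at regions on the other chromosomes, so the prediction was not met. A batch or a reaction efficiency that goes with the medium could raise such reads too, so the test cannot decide on their origin. A smaller number of gained peaks where most peaks stand far above the threshold in every library may remain as an explanation of the low ratio and was not tested.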

How the results depend on the processing

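The cutoffs on −log10 p and on pileup and the alternatives for chromosomes were chosen after the data were seen. The ratio of peak numbers stayed between 1.62 and 1.85 in each alternative run, and the geometric mean over same-numbered libraries (replicate block) was 1.73; taking equal numbers of peaks fixes it and gives no value. Gained regions outnumbered lost ones in each alternative, with the smallest excess for equal numbers of top peaks, 1840 gained and 752 lost, where the full-medium lists reach down to weaker peaks than the cystine-restricted ones by construction. Lost regions numbered 85 at a −log10 q of at least 5, 87 at a pileup of at least 10 times the background (added later) and 859 with a reciprocal overlap of 50%, since that setting also separates overlapping peaks of different width. With 1 library left out, 7691 to 15954 regions were gained and 369 to 2838 lost; within same-numbered pairs (replicate block) 19890 were gained and 2723 lost in pair 1 and 15483 and 4531 in pair 2, fewer libraries being required in both cases. The deviations of same-numbered libraries from their media had a correlation of 0.01 over regions in all 4 libraries, and 2 numbers are too few to pair the samples. The mean Jaccard index within media exceeded that across media by 9.48 percentage points, by 12.4 at a −log10 q of at least 5 and by 6.82 with equal numbers; the excess of full-medium peaks found under cystine restriction was 3.92 with equal numbers and 6.53 with reciprocal overlap. With reciprocal overlap, 2.89% of the strongest and 68.2% of the weakest decile were gained, and 0.346% and 26.2% lost. With equal numbers 37.2% of the weakest decile were gained and 27.3% lost, and at a −log10 q of at least 5, 4.48% of the weakest decile were lost. Apart from what is stated, the cause was not tested. The low gained share of chromosome 19 and the high share of chromosome 15 kept direction and an adjusted p under 0.05 by Fisher's exact test in the 7 alternatives run for them, with the differences from all chromosomes at −10.2 to −5.22 and 6.14 to 10.1 percentage points. Gene lists, start sites, motifs and the CBS locus were not run. Depth limits the weakest regions, as the lowest listed summit pileup was 6 tags in cystine-restricted replicate 2 and 7 in the other libraries.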

Other observations

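The tests of depth and of threshold effects were chosen after the results they measure had been seen. The comparison of pileups and the gained bounds were not planned, and the chromosome tests were chosen because the shares of chromosomes 19 and 15 had been seen. Where ATF3 peaks were present in both media, they were as a rule higher under cystine restriction. At the 10331 regions with a peak in all 4 libraries, the recovered summit pileup over the genome background changed by a median of 0.53 on the log2 scale (interquartile range 0.29 to 0.78), and 92.0% of regions were above 0. The 4 comparisons of single libraries across media had medians of 0.41 to 0.66, against 0.08 between the cystine-restricted and 0.16 between the full-medium libraries. The median was 0.30 in the decile of lowest pileup, where 79.6% were above 0, 0.61 in deciles 7 and 8 and 0.62 in decile 9, and 0.39 at the 100 highest pileups, 78% of which were above 0. These regions had to be listed in both full-medium libraries. Near the threshold this can keep mainly those with a high full-medium pileup, so the low deciles may understate the change. Among the strongest regions the direction differed: at the region on chromosome 1 from 121484286 to 121485509 the pileup was 1167 and 1199 times the background under cystine restriction and 1459 and 1466 times in full medium, and at the region on chromosome 7 from 61968641 to 61969741 it was 714 and 780 against 931 and 983 times, while on chromosome 18 from 107508 to 108675 it was 3798 and 3864 against 2584 and 2223 times. Peaks were not filtered for repeated sequence, so pileups this high need not be ATF3 binding.

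The full-medium lists allow only a lower bound on the observed change in pileup at gained regions. Setting their pileup against the lowest pileup that the full-medium lists would have shown, with the local background assumed to be the same share of the genome background, gave a median bound of 1.64 (interquartile range 1.43 to 1.91). The bound was at least 2 in 1093 of 5685 regions (19.2%) and at least 3 in 97, and the changes themselves are not known. Gained regions were chosen by these same peak calls, which pushes the bound up. It is therefore not a smallest underlying change, and no such bound was computed for the mixed pairs.

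The excess of 5685 gained over 173 lost regions was set against 3 explanations. The last of them, a common factor on all pileups, could be technical or an effect of the medium. Lower depth in full medium is argued against by the background pileup, 1.02 times that of the cystine-restricted libraries, and by the deeper full-medium library, which listed 19132 peaks against 29607 in the shallower cystine-restricted one. Peaks scattering about the threshold with no difference in signal are argued against because, with equal numbers of top peaks, a setting that trims the cystine-restricted lists most, the cystine-restricted pair had 1840 regions of its own, 3.17 times the 580 of the highest pair mixed across media, where scatter alone would give like numbers. One common factor that multiplied all pileups alike would leave the changes in separate pairs of libraries unrelated across regions. After accounting for pileup and local background, they had a correlation of 0.41 or 0.42 in the 2 ways to pair the libraries. The correlation is over regions, which are not independent replicates. Such a uniform factor is therefore not the whole cause. A more efficient reaction need not act uniformly, since regions may differ in how much of their pileup depends on the antibody. Without a library made without the ATF3 antibody, the test cannot decide on it. A more efficient reaction, a uniform factor as part of the cause, a sequence-dependent difference between the libraries, a batch that goes with the medium and an effect of cystine restriction itself all stay open, since the labels give no batch and no spike-in or other control was used here.

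The gained share of chromosomes 19 and 15 was set against the strength of their peaks and gene density, and that of chromosome 15 also against copy number. Copy number of chromosome 19 was not tested. Standardising for strength decile left a chi-square of 96.0 on 22 degrees of freedom (p = 3.1e-11), with 0.712 times the expected number of gained regions on chromosome 19 and 1.17 times on chromosome 15. Strength as parted into these deciles is therefore not the whole cause. Differences of strength within a decile were not accounted for, and the chi-square treats regions as independent. The standardised ratio had a Pearson correlation of −0.75 with protein-coding genes per Mb over 23 chromosomes (permutation p = 0.00056, adjusted over 4 relations 0.00075; Spearman −0.48, permutation p = 0.022, adjusted 0.029). This met a condition set before the correlation was computed. The low share of chromosome 19, the most gene-dense at 24.6 genes per Mb, had been seen by then, so the condition was not independent of these data. Without chromosomes 17 and 19, over a narrower range of 2.94 to 9.64 genes per Mb, Pearson was −0.30 (permutation p = 0.19) and Spearman −0.31 (permutation p = 0.17), so the relation was not detectable without them and gene density remains a possible explanation. A difference in copy number of chromosome 15 between the cultures would raise its common regions, and those above the median pileup rose by 0.11 more than on other chromosomes (95% bootstrap interval 0.04 to 0.19) and those below it by 0.02 (−0.06 to 0.13), so both intervals lie below 0.2 and a smaller shift stays open. A concentration of gained sites away from gene-dense chromosomes remains a hypothesis, which an hg19 annotation would test directly.

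Peak density itself followed gene density in both media. Over 23 chromosomes, protein-coding genes per Mb and peaks per Mb had a Pearson correlation of 0.90 in full medium and 0.88 under cystine restriction (both with the smallest p that 100000 permutations can give, 1e-05, adjusted 2e-05), with Spearman 0.75 (permutation p = 8e-05) and 0.78 (permutation p = 5e-05), and without chromosomes 17 and 19 Pearson was 0.66 and 0.70 and Spearman 0.67 and 0.72.

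A hypothesis that gained regions cluster was negative. Of the gained regions, 36.1% had another gained region within 50 kb, against a median of 36.3% (95% of draws between 34.9% and 37.6%) in 1000 random draws of reproducible cystine-restricted regions matched on chromosome and strength decile (permutation p = 0.60).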
